A study of Mus musculus with 6 samples.

How the data were processed

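The data are RNA sequencing counts from 6 libraries of mouse epidermis, 3 from skin treated with a gel that held AKBA and 3 from skin treated with a blank gel. AKBA is the usual abbreviation of acetyl-11-keto-β-boswellic acid, a triterpenoid of Boswellia resin. The titles gave each library its group and its number within the group. Per the labels' protocols, the epidermis of wild-type C57BL/6 mice was separated from the dermis with the enzyme Dispase II, RNA was extracted with TRIzol, and libraries were made with a TruSeq RNA kit and read on an Illumina HiSeq. The descriptions of the control libraries carry the letters IMQ, which the labels do not spell out, so the control group is called only control gel here. Whether the skin of either group had a further treatment beside the gel is not given in the sources used here. A further treatment would change what the comparison of AKBA gel and control gel means, so the values describe these libraries as labelled. Nothing in the labels says that the 3 libraries of a group came from separate animals, so the p-values measure only the spread between these libraries, which may be technical. Libraries of a group differed by more than sampling noise (chi-square over degrees of freedom at least 30.5), so each was counted as 1 sample.

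The authors deposited 1 table of 47729 genes with a count and an FPKM value for each library, beside their own comparison of the groups. The counts were whole numbers, and whether the authors rounded them from estimates is not given in the sources used here. Per the submitters' processing notes, CASAVA 1.8, RSEM and edgeR were used and the genome build was GRCm38, and the roles of these tools, their order and the annotation release are not given in the sources used here. The deposited FPKM values were the counts divided by the column total and by 1 length per gene, and over 9795 genes with at least 200 counts in each library the implied lengths differed between libraries by at most 1.02 times. The FPKM values were used for this check only. Per the file headers, the deposited comparison gives a log2 fold change of AKBA gel over control gel, a p-value and an adjusted p-value for each gene, and the method behind them is not stated there. The authors also deposited the broad Gene Ontology terms of the genes they called. KEGG pathway identifiers were not used here. Strand-specific counting is not stated, so reads of overlapping or antisense genes cannot be told apart.

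All 6 per-library count columns were used as deposited. Of the 47729 genes, 19134 had no count in any library. Fold changes, standard errors and p-values came from edgeR 4.0.16 in R 4.3.3 with TMM scaling, the default low-count filter (17023 genes kept), and the 2-sided quasi-likelihood F test, with Benjamini-Hochberg adjustment and a threshold of 0.05. The standard error of a log2 fold change was its size divided by the square root of F. Levels are CPM, counts scaled to a common library size after TMM scaling, as mean ± SD over 3 libraries. Gene lists were tested with camera from limma 3.58.1 at a preset correlation between genes of 0.01, with adjustment over 26 lists. Of these 13 describe epidermal responses and 13 are called marker lists. The marker lists hold markers of cell types, except for the list of immediate early and stress genes, which marks no cell type. Counts of marker lists and of their members include this list. Beside camera at the preset correlation stand camera with an estimated correlation, the rotation test fry, and the number of members past the threshold when p-values are adjusted over the list alone. A list score is the mean of its members' log2 CPM, with a prior count of 2. The depth of 19066045 to 22760432 counts sets a floor of 0.132 to 0.157 CPM for 3 counts, which covers counting error only. Gene positions are those of GENCODE M21 on GRCm38, in which 47224 of the gene identifiers were found.

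The groups, tests, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule took the 10 largest changes per direction among genes past the threshold whose groups did not overlap and whose mean was at least 5 CPM. It also took up to 4 members of each list past the threshold, or else the 2 members with the highest level. Alox5, Nfkb1, Rela, Mat2a, Krt5, Krt10, Krt16, Il17a, S100a8 and S100a9 were named whatever their values. Because edgeR called no gene, the first part of the rule named 0 genes. The genes called by DESeq2 1.42.0 were put through the same rule in their place, and members past the threshold over their list alone were named, both after their values had been seen. Of 13 gene families examined after the results had been seen, 1 is not reported here.

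The alternatives were DESeq2 size factors within edgeR, no filter beyond a count in any library, a stricter filter of 5 CPM in 3 libraries, the replicate number as a block, each library left out in turn, the DESeq2 Wald test with default settings, a minimum 2-fold change, an adjusted p under 0.01, an estimated correlation, and fry. After seeing the data 3 alternatives were added. The stricter filter, planned for the count of genes, was extended to the lists. Another left out AKBA replicate 2 and control replicate 3 at once, the lowest and the highest in Krt6a. The last tuned the filtering of DESeq2 to 0.05, and it was run first by mistake.

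The programs were tested on simulated data of 17023 genes for the comparison of AKBA gel and control gel, in which 200 single genes were changed and a further list of 25 genes was lowered 2-fold. The edgeR step recovered 67% of 100 genes changed 2-fold and 97% of 100 genes changed 4-fold, with 14 unchanged genes among 193 calls, which include members of the list. The DESeq2 step recovered 83% and 98% of these genes, with 56 unchanged genes among 258 calls. The list of 25 genes was found as lower, and 2 of 200 unchanged lists had a camera p under 0.05. The simulated genes were drawn independently, so this cannot show how camera behaves for lists whose genes vary together. The recovered shares of single genes need not hold in the real libraries either. The lack of edgeR calls there does not show that few genes changed. In the real libraries the estimated correlation ran from -0.015 for chemokines to 0.63 for the stress keratin and SPRR list and 0.883 for the hair follicle list. Exact tests used SciPy 1.17.1, and figures were drawn with matplotlib 3.10.9.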

Results

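Messenger RNA was counted in the epidermis of mice whose skin was treated with AKBA gel (3 libraries) or with a blank control gel (3 libraries), and the design asks how the gel with AKBA changed epidermal gene expression. The AKBA libraries held 20859697, 19066045 and 21992741 counts (replicates 1 to 3), and the control libraries 20568296, 22217153 and 22760432. The 10 most abundant genes took 9.14% to 10.6% of the counts of a library. Fibroblast markers took 2.30% to 4.50% and skeletal muscle markers 0.722% to 1.32%, beside 1.34% to 3.38% for the basal keratinocyte list. The libraries thus held transcripts of dermis and muscle too, and the values below describe this mixed tissue. Across genes, the correlation of log2 CPM was 0.977 to 0.982 between libraries of a group and 0.958 to 0.988 between libraries of different groups. The first principal component held 42.1% of the variance, with the AKBA libraries at -26.3, -43.8 and -8.74 and the control libraries at -0.0812, 32.8 and 46.2.

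Keratins and small proline-rich proteins of activated epidermis were lower under AKBA gel. Krt6a, a keratin induced in wounded or hyperproliferative epidermis (chromosome 15, 101689910 to 101694307), was at 798 ± 531 CPM with AKBA gel and 6056 ± 4013 CPM with control gel (SD, n = 3 each). Its partner Krt16 was at 1262 ± 696 against 5597 ± 3461 CPM, and Sprr2g, an SPRR2 gene annotated as a polymorphic pseudogene, at 5.30 ± 2.92 against 122.5 ± 123.8 CPM. For each of these 3 genes every AKBA library lay below every control library. Of the 24 measured members of this list, 13 fell and 1 rose when p-values were adjusted over the list alone. By edgeR the log2 fold changes were -2.92 ± 0.80 (SE) for Krt6a, -2.15 ± 0.61 for Krt16 and -4.52 ± 0.84 for Sprr2g, with adjusted p over the list alone of 0.0158, 0.0174 and 0.00825. The member that rose was Sprr4 (1.33 ± 0.36). The median of the list was -1.79, and camera placed it below the other genes (adjusted p = 4.84e-16), a call lost with an estimated correlation (adjusted p = 0.504). Without control replicate 3 the median was -1.13 with 10 members lower, and without AKBA replicate 2 and control replicate 3 it was -0.77 with 12 lower. Immediate early genes, which respond to handling and stress of a tissue, had a median of -0.50 in the same libraries. Reads of SPRR2 genes and of Krt6a and Krt6b can be shared between close copies, so the split between copies is uncertain.

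Genes of the cornified envelope and the upper epidermal layers went in opposite directions. All 6 LCE3 genes, late cornified envelope genes known to be induced after barrier injury, fell, among them Lce3d (25.2 ± 14.7 against 186 ± 118 CPM) and Lce3c (48.0 ± 12.5 against 183 ± 106 CPM). The genes that rose were Flg2, a filaggrin relative of the granular layer (404 ± 226 against 107 ± 50.3 CPM), the protease inhibitor Cst6 (1032 ± 383 against 460 ± 110 CPM), the keratin Krt77 and Lce1m. By edgeR the log2 fold changes were -2.88 ± 0.62 (SE) for Lce3d, -1.93 ± 0.40 for Lce3c, 1.92 ± 0.49 for Flg2 and 1.17 ± 0.31 for Cst6, with adjusted p over the list alone between 0.0221 and 0.04. The other 34 of the 44 measured members did not pass over the list alone. These included Lor, the main envelope protein (1.27 ± 0.42), and the suprabasal keratins Krt10 (19341 ± 5814 against 9999 ± 3447 CPM, log2 fold change 0.95 ± 0.38) and Krt1 (0.50 ± 0.34). The median of the list was 0.37 and camera placed it above the other genes (adjusted p = 0.032, and 0.801 with an estimated correlation). The camera call was lost without AKBA replicate 1 (adjusted p = 0.281), AKBA replicate 2 (0.479), control replicate 1 (0.171) or control replicate 2 (0.707), and with AKBA replicate 2 and control replicate 3 both left out (0.877). The number of members that rose was 0 without AKBA replicate 1, AKBA replicate 2, control replicate 2 or control replicate 3 and with the stricter filter, and 20 without AKBA replicate 3. Without AKBA replicate 2 no member fell over this list.

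**Figure D1:**
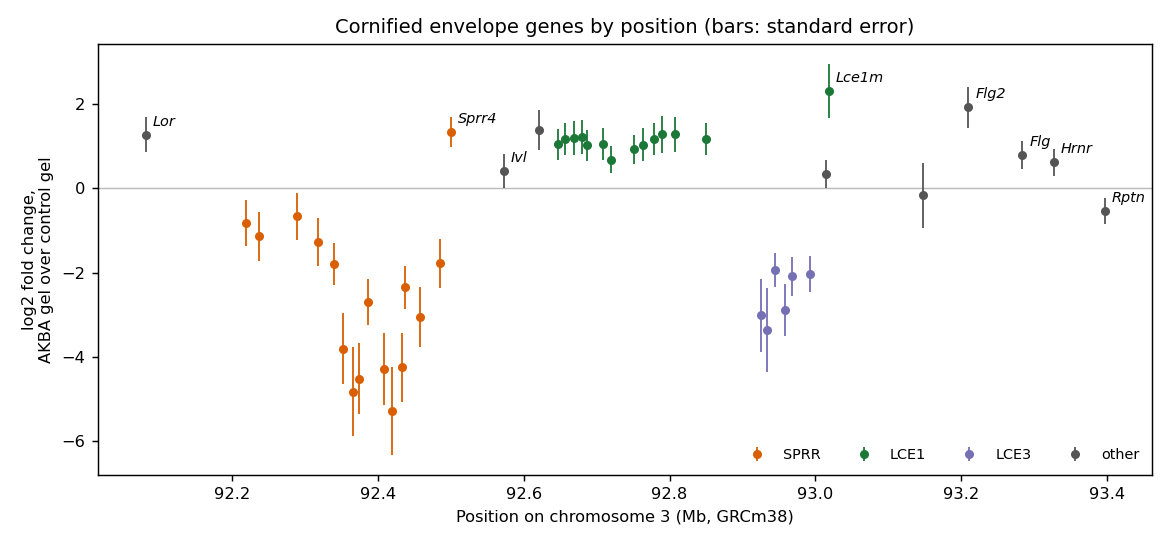
Log2 fold change of AKBA gel over control gel (vertical axis, points with standard error) for tested genes of the epidermal differentiation complex by position on chromosome 3 (horizontal axis, Mb, GRCm38). The SPRR genes other than Sprr4 and the LCE3 genes lie below 0, and the LCE1 genes, with Lce1m at 2.32, lie above 0.

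Many of these genes are neighbours. The epidermal differentiation complex spans positions 90511034 to 93564643 of chromosome 3 in the genes tested here (59 genes). Sprr2f (92365187 to 92366442, log2 fold change -4.82 ± 1.05), Sprr2g and Sprr2i (92407991 to 92409271, -4.27 ± 0.85) lie in the SPRR block. Lce3d (92957390 to 92958505) lies between the LCE1 block and Lce1m (93017810 to 93019060, 2.32 ± 0.65). Sprr2a1 and Sprr2a2 overlap in the annotation, and their values cannot be kept apart.

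**Figure D2:**
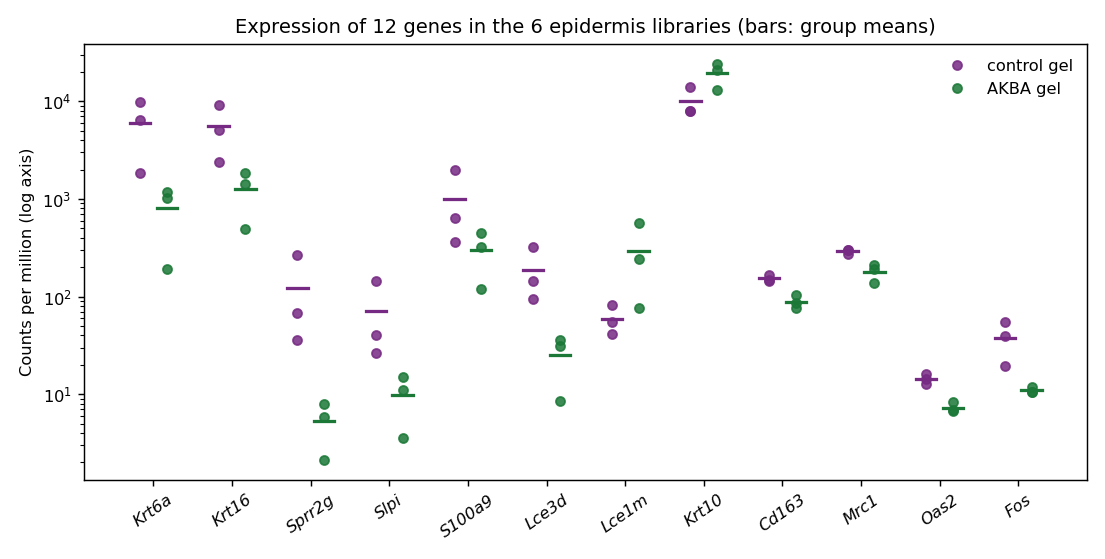
CPM (vertical axis, log scale) of 12 genes in each of the 3 control gel libraries and 3 AKBA gel libraries, with a bar at each group mean. Krt6a lies between 193 and 1183 CPM with AKBA gel and between 1850 and 9843 CPM with control gel, and Oas2, Cd163 and Mrc1 also show no overlap of the groups.

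Some antimicrobial peptides and alarmins were lower under AKBA gel. Of 21 measured members 5 fell over the list alone, namely the β-defensins Defb3 and Defb4, the protease inhibitor Slpi, S100a7a and haptoglobin, Hp. Slpi was at 9.82 ± 5.74 against 70.5 ± 64.7 CPM (log2 fold change -2.83 ± 0.74, edgeR adjusted p over the list alone = 0.0417) and Hp at 123 ± 38.0 against 258 ± 97.0 CPM (-1.07 ± 0.31, 0.0463). The abundant alarmin pair S100a8 (292 ± 108 against 687 ± 578 CPM) and S100a9 (297 ± 168 against 999 ± 868 CPM) did not pass, with log2 fold changes of -1.23 ± 0.58 and -1.75 ± 0.69. With 1 library left out these ranged from -1.59 to -0.28 and from -2.17 to -0.76. The list median was -0.74 (camera adjusted p = 0.000487, and 0.517 with an estimated correlation). No member passed over the list alone without AKBA replicate 1, AKBA replicate 2 or control replicate 3 or with the stricter filter. Without AKBA replicate 3 there were 2 lower members, without control replicate 1 there were 6 lower and 2 higher, and without both AKBA replicate 2 and control replicate 3 there was 1 lower. The median was -0.28 without control replicate 3 and -0.10 without both AKBA replicate 2 and control replicate 3.

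Signalling lists of inflammation shifted by small amounts. In the NF-κB and Toll-like receptor list, Bcl3, an IκB family protein (15.7 ± 0.470 against 33.2 ± 11.2 CPM), and Tlr8 (10.6 ± 2.20 against 18.6 ± 0.884 CPM) fell among 30 members, with log2 fold changes of -1.08 ± 0.25 and -0.82 ± 0.17 and an edgeR adjusted p over the list alone of 0.0395 for each. The list median was -0.21 (camera adjusted p = 0.0011, and 0.504 with an estimated correlation). Nfkb1 (114 ± 9.71 against 139 ± 8.79 CPM, log2 fold change -0.29 ± 0.11) and Rela (-0.23 ± 0.13) did not pass, nor did Traf6 (97.5 ± 9.75 against 109.8 ± 16.7 CPM). Of 28 interferon-stimulated genes only Oas2 fell (7.24 ± 0.890 against 14.4 ± 1.68 CPM, log2 fold change -0.99 ± 0.16, edgeR adjusted p over the list alone = 0.00932), and the list median was -0.22 (camera adjusted p = 0.00249, and 0.742 with an estimated correlation). Its most abundant members Stat2 (34.1 ± 2.04 against 35.7 ± 4.50 CPM) and Irf9 (34.5 ± 2.31 against 31.7 ± 6.38 CPM) did not pass. Without control replicate 1 the interferon median was 0.06 and its camera call was lost (adjusted p = 0.754), as it was with the stricter filter (16 members tested, median -0.02, adjusted p = 0.562). The interferon medians were -0.36 without control replicate 2 and -0.40 without control replicate 3. No NF-κB list member passed without AKBA replicate 1, AKBA replicate 2 or control replicate 3, 1 passed without control replicate 1 and 5 passed without AKBA replicate 3 (4 lower and 1 higher). Oas2 did not pass without AKBA replicate 1 or AKBA replicate 2.

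With all 6 libraries no member passed over the list alone in the lists of inflammatory cytokines (12 tested, median -0.14, camera adjusted p = 0.19), chemokines (16 tested, -0.20, 0.356) and eicosanoid enzymes and receptors (28 tested, -0.09, 0.0848). The cytokine list passed as lower by camera without AKBA replicate 1 (adjusted p = 7.23e-05), AKBA replicate 2 (0.00213) or AKBA replicate 3 (median -1.07, 0.021), with 17 members tested. It also passed as lower without control replicate 1 (-0.87, adjusted p = 1.81e-07, with 6 of 17 members lower over the list alone) or control replicate 2 (-0.31, 0.0144). Without the low-count filter it passed as lower too (23 tested, adjusted p = 2.2e-05, with 8 members lower and 1 higher). With the stricter filter 1 of 7 members was lower over the list alone. The eicosanoid list passed as lower without AKBA replicate 2 (adjusted p = 0.0319), control replicate 1 (0.03, with 4 members lower and 1 higher) or the filter (0.0352). The chemokine list passed as lower without the filter (0.0122). With an estimated correlation and all 6 libraries the camera adjusted p was 0.576 for each of these 3 lists, and the calls without a library or the filter rest on the preset correlation. Among their most abundant members, Il1f5, the IL-36 receptor antagonist, was at 806 ± 226 against 512 ± 122 CPM and Il1f8 at 164 ± 34.1 against 179 ± 57.0 CPM. Cxcl12 was at 145 ± 51.1 against 178 ± 32.1 CPM, Ccl8 at 66.1 ± 7.39 against 84.9 ± 24.1 CPM, and the phospholipases Pla2g2f and Pla2g4e at 695 ± 209 against 514 ± 136 and 148 ± 37.7 against 292 ± 149 CPM. Alox5, the 5-lipoxygenase that AKBA is known to inhibit, was at 11.5 ± 1.41 against 13.1 ± 3.79 CPM (log2 fold change -0.18 ± 0.23). Il17a was below the filter, with 9, 2 and 4 counts in the AKBA libraries and 13, 6 and 3 in the control libraries. Of 23 cytokines listed 12 were tested, so the others are not shown to be unchanged. Among those below the filter, Il19 had 1, 0 and 3 against 4, 119 and 142 counts. Il24 had 0, 0 and 5 against 1, 77 and 31, and Il6 1, 1 and 3 against 2, 45 and 11. Il23a had 2, 0 and 3 against 3, 13 and 20, and Il22 2, 0 and 1 against 0, 2 and 1.

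The basal layer list had a median of -0.40 (16 members, camera adjusted p = 0.00249, and 0.541 with an estimated correlation), and none of its members passed over the list alone. The basal keratin Krt14 was at 6775 ± 2154 against 15735 ± 8051 CPM (log2 fold change -1.22 ± 0.45), and its partner Krt5 was at 4545 ± 347 against 5350 ± 1425 CPM (-0.24 ± 0.26). Without control replicate 1, 8 members were lower and 2 higher over the list alone. Without control replicate 3 the median was -0.25, and the camera call was lost with AKBA replicate 2 left out as well (median -0.19, adjusted p = 0.0681).

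Proliferation and metabolic lists did not pass with all 6 libraries, and no member of them passed over the list alone. The cell cycle list had a median of -0.11 over 36 genes (camera adjusted p = 0.0668), with Mki67 at 252 ± 84.9 against 271 ± 75.0 CPM and Top2a at 144 ± 43.9 against 150.3 ± 34.4 CPM. The methionine cycle and DNA methylation list had a median of -0.10 (adjusted p = 0.19). In it Mat2a, which makes S-adenosylmethionine, was at 137 ± 7.07 against 187 ± 17.6 CPM with no overlap of the groups (log2 fold change -0.45 ± 0.12, edgeR adjusted p over all genes = 0.331, DESeq2 adjusted p = 0.0495), and Tet3 was at 197 ± 20.2 against 186 ± 14.2 CPM. Lipid synthesis genes had a median of -0.08 (adjusted p = 0.655), with Scd1 at 3004 ± 1230 against 2350.2 ± 309.9 CPM and Elovl4 at 1559 ± 498 against 1212 ± 63.1 CPM. NRF2 target genes had a median of -0.06 (adjusted p = 0.655), with Me1 at 233 ± 55.4 against 163 ± 26.0 CPM and Pgd at 176 ± 32.1 against 174 ± 18.9 CPM. The cell cycle list passed as lower by camera without AKBA replicate 2 (adjusted p = 0.042), AKBA replicate 3 (median -0.31, 7.74e-05), control replicate 1 (-0.20, 0.00683) or control replicate 3 (-0.19, 0.00553). It passed as lower too with AKBA replicate 2 and control replicate 3 both left out (-0.17, 0.0034) and without the low-count filter (0.0241). Its median was 0.02 without AKBA replicate 1 and 0.05 without control replicate 2. Lipid synthesis genes passed as lower without AKBA replicate 1 (-0.24, 0.00416) and as higher with the pair left out (0.14, 0.0169). The methionine cycle list passed as lower without AKBA replicate 3 (-0.21, 0.0388, with 1 member lower). These calls rest on the preset correlation, and with all 6 libraries the adjusted p at an estimated correlation was 0.882 for the cell cycle (estimated correlation 0.819), 0.96 for lipid synthesis and 0.782 for the methionine cycle list. The hair follicle markers had medians of -1.13 without AKBA replicate 3 and 2.37 without control replicate 2, so their share may bear on the cell cycle medians, which was not tested.

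Markers of macrophages were lower under AKBA gel. Of 17 macrophage markers 6 fell over the list alone, among them the scavenger receptor Cd163 (88.9 ± 14.6 against 154 ± 12.0 CPM, log2 fold change -0.79 ± 0.14, edgeR adjusted p over the list alone = 0.0109) and the mannose receptor Mrc1 (179 ± 35.8 against 292 ± 14.9 CPM, -0.71 ± 0.17, 0.018). Lyz2, the most abundant, was at 705 ± 16.5 against 836 ± 207 CPM and did not pass. The macrophage median was -0.44 (camera adjusted p = 5.98e-10, and 0.504 with an estimated correlation). Markers of the dermis moved the same way, with medians of -0.39 for fibroblast genes (adjusted p = 0.00025, and 0.517 with an estimated correlation) and -0.43 for endothelial genes (6.66e-05, and 0.517). No fibroblast or endothelial marker passed over its list alone, with Col3a1 at 7268 ± 1036 against 9892 ± 2251 CPM, Col1a1 at 6619 ± 1365 against 8300.1 ± 3317 CPM, Vwf at 96.9 ± 35.6 against 135 ± 32.2 CPM and Pecam1 at 74.0 ± 15.3 against 105 ± 11.3 CPM. The number of macrophage members that passed was 0 without AKBA replicate 1, 4 without AKBA replicate 3 or control replicate 1, 1 without control replicate 3, and 0 without both AKBA replicate 2 and control replicate 3. The endothelial median was -0.21 without AKBA replicate 2, and 3 fibroblast markers were lower without AKBA replicate 3.

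Of 10 neutrophil markers 3 fell over the list alone, the gelatinase Mmp9 (3.74 ± 1.95 against 15.4 ± 7.32 CPM, log2 fold change -2.03 ± 0.51, edgeR adjusted p over the list alone = 0.0467) and the lectin receptors Clec4d (-1.95 ± 0.57) and Clec4e (-1.79 ± 0.56). The median was -0.89 (camera adjusted p = 0.000112, and 0.504 with an estimated correlation). Of the 17 neutrophil genes listed 10 were tested. Ly6g had 0 counts in all 6 libraries, Ngp 0 to 2 and Retnlg 1 to 20. Mmp8 was tested at 3.44 ± 1.25 against 3.76 ± 0.991 CPM (log2 fold change -0.12 ± 0.33). A change in neutrophils thus cannot be read from this list alone. The list also holds stefin genes that keratinocytes express. Its most abundant members BC100530 (962 ± 229 against 1359 ± 728 CPM) and Stfa2 (28.5 ± 12.9 against 76.7 ± 56.8 CPM) did not pass. T cell markers had a median of -0.27 (camera adjusted p = 0.0385, and 0.576 with an estimated correlation) with no member past the threshold, Thy1 at 91.9 ± 14.3 against 135 ± 36.4 CPM and Cd4 at 7.49 ± 3.24 against 11.7 ± 2.96 CPM. No neutrophil marker passed without AKBA replicate 1, AKBA replicate 2, control replicate 2 or control replicate 3. Without AKBA replicate 3 or control replicate 1 there were 5 and 6 lower markers, each beside 1 higher marker, with medians of -1.38 and -1.46. The T cell call was lost without AKBA replicate 2 (adjusted p = 0.29), control replicate 1 (0.258, median -0.16) or control replicate 3 (0.0689), and with the stricter filter (0.137, 7 members tested). Under that filter 1 neutrophil marker passed.

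Some immediate early genes fell and sebaceous gland genes stood higher. Of 16 early genes 5 fell over the list alone, with Fos at 10.9 ± 0.813 against 37.7 ± 17.6 CPM (log2 fold change -1.79 ± 0.34, edgeR adjusted p over the list alone = 0.0117), Fosb, Nr4a1, Junb and Atf3, and Egr2 rose (62.3 ± 7.44 against 37.6 ± 6.24 CPM, 0.73 ± 0.15). The median was -0.50 (camera adjusted p = 6.29e-05, and 0.517 with an estimated correlation), and the heat shock genes Hspa8 (1130 ± 70.1 against 1428 ± 191 CPM) and Hspa1b (210 ± 8.27 against 231 ± 49.1 CPM) did not pass. All 16 sebaceous gland genes had a log2 fold change above 0 (median 0.63, camera adjusted p = 5.53e-06, and 0.517 with an estimated correlation), and 0 passed over the list alone, with Far2 at 459 ± 196 against 283 ± 111 CPM and Fa2h at 462 ± 186 against 249 ± 101 CPM. Among the early genes 0 passed without AKBA replicate 1, 1 higher and 1 lower without AKBA replicate 2, 3 lower without control replicate 2 or control replicate 3 (median -0.23 without the latter), 9 lower without control replicate 1, 2 lower with the stricter filter and 0 without both AKBA replicate 2 and control replicate 3. The sebaceous median was 0.29 without AKBA replicate 1 and 0.41 without control replicate 3, and 1 sebaceous gene was higher over the list alone without AKBA replicate 3.

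The other 6 marker lists did not pass with all 6 libraries. Their medians were 0.11 for Langerhans and dendritic cells (camera adjusted p = 0.409; Cd74 at 516 ± 138 against 464 ± 52.3 CPM and H2-Aa at 259 ± 84.3 against 230 ± 17.9 CPM), 0.02 for melanocytes (0.827), 0.04 for skeletal muscle (0.396), -0.12 for adipocytes (0.387), 0.26 for erythroid cells (0.649) and -0.10 for the hair follicle (0.872). Melanocyte, muscle and hair follicle lists had a median and a mean or test of different sign. Dct and Ednrb were at 56.7 ± 26.9 against 54.3 ± 25.6 and 48.1 ± 11.8 against 56.4 ± 4.37 CPM, Acta1 and Myh1 at 2398 ± 509 against 1977 ± 529 and 1822 ± 549 against 1142 ± 242 CPM, Car3 and Lpl at 835 ± 179 against 842 ± 254 and 398 ± 91.6 against 425 ± 96.0 CPM, and Hbb-bs and Hba-a1 at 81.9 ± 36.0 against 67.0 ± 14.7 and 54.6 ± 25.8 against 45.6 ± 7.89 CPM. The hair keratin Krt71 varied widely within groups (298 ± 319 against 330 ± 491 CPM), as did Tchh (319.8 ± 351.0 against 422 ± 597 CPM). The hair follicle median passed as higher without AKBA replicate 1 (0.42, camera adjusted p = 0.000767) or control replicate 2 (2.37, 3.26e-06), and as lower without control replicate 3 (-0.57, 0.0328) or without both AKBA replicate 2 and control replicate 3 (-0.47, 0.0039). The skeletal muscle list passed as higher without control replicate 1 (median 0.47, adjusted p = 0.00282), and the adipocyte list as lower without control replicate 2 (-0.29, 0.000642). These calls rest on the preset correlation, and with all 6 libraries the adjusted p at an estimated correlation was 0.971 for the hair follicle (estimated correlation 0.883) and 0.882 for the muscle and adipocyte lists.

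**Figure D3:**
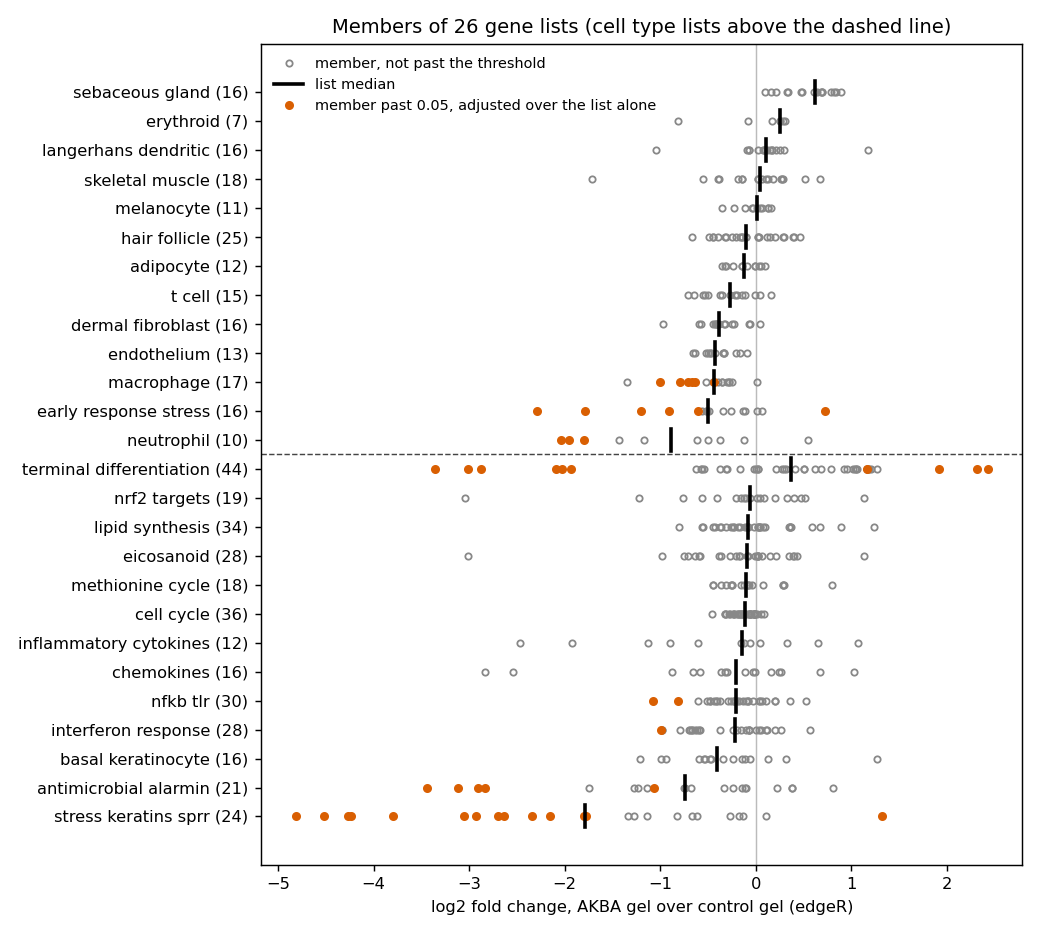
Log2 fold change of AKBA gel over control gel (horizontal axis, edgeR) for the tested members of 26 gene lists (vertical axis, number tested in brackets), with a bar at each list median and filled points for members past 0.05 adjusted over the list alone. The stress keratin and SPRR list has the lowest median, -1.79, and the sebaceous list the highest, 0.63.

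Gene by gene, edgeR placed 0 of 17023 genes past an adjusted p of 0.05 (smallest 0.331), with 2291 genes at an unadjusted p under 0.05 (1098 higher, 1193 lower) where chance gives 851. Another division of the same 6 libraries into 3 and 3 gave 2321 such genes, so the excess over 851 cannot be credited to the gel. The DESeq2 Wald test called 292 genes (89 higher, 203 lower), and all 286 of them that edgeR tested had an unadjusted p under 0.05 there. In the simulated data 56 of 258 DESeq2 calls were unchanged genes, against 14 of 193 edgeR calls. More of the DESeq2 calls may thus be false than their adjusted p states. Without control replicate 1, edgeR called 14 genes. The groups did not overlap for 3129 genes (18.4%, where chance gives 10%), a share that was not computed for other divisions of the libraries. An adjusted p under 0.05 was given to 389 genes in the authors' deposited table, and 273 of these were called there (115 higher, 158 lower). Of the 389 genes in the authors' deposited table, 244 were also DESeq2 calls here, and all 244 had the same direction.

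Among the DESeq2 calls, named after their values were seen, the largest increases included Paqr7, a membrane progestin receptor (chromosome 4, 134496697 to 134510235; 62.0 ± 19.5 against 17.1 ± 5.49 CPM), Cyp2b19, an epidermal cytochrome P450 of arachidonic acid (199.6 ± 98.3 against 58.1 ± 19.9 CPM), Skint4 (49.2 ± 13.1 against 16.4 ± 11.8 CPM), Bbox1, the last enzyme of carnitine synthesis (53.6 ± 21.2 against 17.9 ± 11.6 CPM), and Serpinb7 (102 ± 50.6 against 37.5 ± 12.4 CPM). Their DESeq2 adjusted p lay between 1.25e-05 for Paqr7 and 0.0203 for Bbox1. Phf24, Gng4, Cobl, Gal3st1 and Slc46a2 completed the 10 increases. Among the 10 decreases were 6 SPRR2 genes, of which Sprr2j-ps, Sprr2f, Sprr2g, Sprr2i and Sprr2k had the 5 largest and Sprr2e a smaller change, and Krt6a, with the smallest of the 10. The others were Epgn, a ligand of the EGF receptor (4.69 ± 1.48 against 44.2 ± 35.9 CPM, DESeq2 log2 fold change -3.24 ± 0.77, adjusted p = 0.00824), the urate oxidase gene Uox (3.05 ± 2.53 against 43.7 ± 38.3 CPM, -3.85 ± 1.07, 0.028) and Sh2d5 (1.26 ± 0.413 against 22.5 ± 16.5 CPM, -4.17 ± 0.87, 0.00138). All 20 genes had an edgeR adjusted p of 0.331.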

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

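Leaving out AKBA replicate 2 and control replicate 3 at once, tuning the filter of DESeq2 to 0.05 and running the lists with the stricter filter were tests chosen after seeing the data, while the other settings were planned. The count of 0 genes from edgeR (2291 at an unadjusted p under 0.05) stayed at 0 with DESeq2 size factors, without a filter, with the stricter filter, with the replicate block, with a 2-fold minimum, at an adjusted p under 0.01 and with that pair left out. It ranged from 0 to 14 with single libraries left out, the 14 coming without control replicate 1, and the DESeq2 Wald test gave 292 genes, or 304 with the tuned filter. The cause of the gap between edgeR and DESeq2 was not tested. DESeq2 size factors shifted the log2 fold changes of single genes by a median of -0.0049 and gave the same counts of lists, 6 response and 7 marker lists, and of members past the threshold over each list alone, 32 and 15. Without the filter there were 10 response lists and 79 response and 37 marker members. With the stricter filter there were 5 response and 6 marker lists and 19 and 11 members, fewer genes were tested, the calls of the interferon and T cell lists were lost, and the hair follicle median was 0.032. An estimated correlation or fry left 0 response and 0 marker lists (lowest adjusted p 0.504 and 0.326, and 0.0594 for the mixed test of fry). With single libraries left out the response lists ranged from 6 to 9, the marker lists from 6 to 9, the response members from 14 to 59 and the marker members from 0 to 21. With the pair left out there were 20 response and 0 marker members, and the calls of the terminal differentiation, basal and T cell lists were lost. Fewer libraries were fitted in these settings, and which property of a left-out library moved a count was not tested.

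The replicate number was also fitted as a block. Same-numbered libraries did not deviate together (correlations of deviations from the group means -0.33 to 0.07, and 2 of 6 libraries correlated best with their own number), so the numbers are not taken to pair the libraries. The block gave 0 genes, 7 response and 7 marker lists, and 28 and 16 members over each list alone. The cell cycle list passed as lower under it (adjusted p = 0.0339). Past the threshold over their list or family alone were 0 NF-κB, 0 interferon and 0 neutrophil members and 0 LCE1, 0 matrix metalloproteinase and 0 claudin genes (2, 1, 3, 13, 2 and 1 without the block), and 9 macrophage, 10 SPRR2 and 10 Skint genes (6, 8 and 7 without it). Serpin B genes and kallikreins had 3 higher and 2 lower genes under the block, against 0 without it. It also turned Car3 (0.018) and the melanocyte median (-0.0025).

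Directions of named genes and lists were the same in 947 and 249 results with the side of the threshold kept, and 42 and 23 results passed only in an alternative. No named gene was called by edgeR, so none lost a call, and lists lost a call in 38 results, of which an estimated correlation and fry account for 13 each. Values that changed sign with the pair left out were those of Alox5 (0.094), BC100530 (0.069), Car3 (0.13), Cd74 (-0.14), Cxcl12 (0.11), Dct (-0.23), H2-Aa (-0.14), Hspa1b (0.023), Il1f8 (0.11), Irf9 (-0.034), Krt5 (0.027) and Lpl (0.13), and the medians of the lists of adipocyte (0.13), cytokine (0.063), lipid synthesis (0.14), melanocyte (-0.23), NRF2 (0.029) and skeletal muscle genes (-0.11). With single libraries left out, sign changes fell within the ranges of Alox5 (-0.38 to 0.016), BC100530 (-0.72 to 0.035), Car3 (-0.24 to 0.18), Cd74 (-0.088 to 0.27), Dct (-0.31 to 0.47), H2-Aa (-0.13 to 0.32), Hba-a1 (-0.18 to 0.53), Hbb-bs (-0.10 to 0.56), Hspa1b (-0.30 to 0.010), Il1f8 (-0.32 to 0.15), Krt71 (-1.32 to 2.66), Lpl (-0.27 to 0.080), Mki67 (-0.40 to 0.13), Pgd (-0.13 to 0.14), Scd1 (-0.020 to 0.58), Stat2 (-0.16 to 0.019), Tchh (-1.70 to 2.02) and Top2a (-0.32 to 0.13). The list medians that did so were adipocyte (-0.29 to 0.0039), cell cycle (-0.31 to 0.046), chemokine (-0.32 to 0.10), erythroid (-0.10 to 0.41), hair follicle (-1.13 to 2.37), cytokine (-1.07 to 0.045), interferon (-0.40 to 0.057), lipid synthesis (-0.24 to 0.069), melanocyte (-0.38 to 0.35), NRF2 (-0.14 to 0.037) and skeletal muscle (-0.18 to 0.47). The cause of these changes was not tested. Depth limits genes such as Il17a, with 2 to 13 counts per library, for which no difference was detectable at this depth.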

Other observations

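The gene families, the Gene Ontology comparison, the hair follicle relations, and the tests of the dermal share, the keratinocyte share, the second axis of within-group variation and the edgeR gene count over other splits were chosen after the results had been seen. Among 13 families examined, p-values from edgeR were adjusted over each family. All 6 LCE3 genes fell, with a median of -2.48 (-1.85 without control replicate 3, -1.49 without both AKBA replicate 2 and control replicate 3), and all 6 passed with any 1 library left out and without that pair. This holds only for p-values adjusted over these 6 genes, chosen after their values were seen. Over the whole terminal differentiation list, which includes them, no gene fell without AKBA replicate 2. Of 12 SPRR2 genes 8 fell, and 8 or 9 did so with any 1 library left out. Of 14 LCE1 genes 13 rose (median 1.17), but 0 passed without AKBA replicate 1, AKBA replicate 2 (median 0.75), control replicate 2 or control replicate 3. The groups overlapped for every LCE1 gene, as AKBA replicate 3 lay below control replicate 1. For example, Lce1b was at 178 against 209 CPM and Lce1m at 76.9 against 81.4 CPM in these libraries.

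All 11 Skint genes, which encode butyrophilin-like membrane proteins of keratinocytes and thymus, had log2 fold changes above 0, and 7 rose, among them Skint6 (33.8 against 8.60 CPM, 1.97 ± 0.57), Skint9 (2.21 ± 0.81) and Skint4 (1.58 ± 0.46). None passed without AKBA replicate 1, AKBA replicate 2, control replicate 2 or control replicate 3. The Skint genes are close copies that can share reads. Of 9 ligands of EGF family receptors 4 fell, Epgn (-3.23 ± 0.65), Nrg1 (-2.46 ± 0.55), Hbegf (10.9 against 57.3 CPM, -2.39 ± 0.56) and Areg (-1.32 ± 0.44), and 3 to 5 did so with any 1 library left out. Of 3 Cyp2b genes 2 rose, Cyp2b19 and Cyp2b23, but 1 without AKBA replicate 1, AKBA replicate 2 or control replicate 2. Of 16 matrix metalloproteinase genes Mmp13 (0.446 against 9.48 CPM) and Mmp9 fell (3 genes with DESeq2 size factors). Without control replicate 1 there were 3, and leaving out any other library gave 0. Of 12 claudins Cldn1 rose (295 against 203 CPM, 0.54 ± 0.13), with 0 without AKBA replicate 1, AKBA replicate 2, control replicate 2 or control replicate 3, and 2 without AKBA replicate 3. The serpin B, kallikrein, IL-36 and stefin families had 0 genes past the threshold with all libraries. Without control replicate 1 there were 4 higher and 3 lower serpin B genes, 3 lower stefins and 2 lower kallikreins, without control replicate 2 there were 3 lower stefins and 2 lower kallikreins, and without AKBA replicate 3 there were 2 higher serpin B genes and 1 higher IL-36 gene. Without the low-count filter there were 4 higher and 3 lower serpin B genes, 5 lower kallikreins and 3 lower stefins. With DESeq2 size factors no family median changed sign, but with 1 library left out those of the serpin B (-0.23 to 0.24), IL-36 (-0.26 to 0.14) and claudin genes (-0.057 to 0.27) did.

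In the authors' deposited table of broad Gene Ontology terms, 31 of 131 annotated genes called lower and 1 of 92 called higher carried locomotion (Fisher's exact test, p = 2.93e-07, adjusted over 52 terms 7.61e-06). For immune system process the authors' deposited table gives 27 of 131 and 7 of 92 (Fisher's exact test, p = 0.00803, adjusted 0.0232). In total 23 terms differed between the directions at an adjusted p under 0.05, and each was carried by a larger share of the genes called lower. In the authors' deposited table these include unspecific terms, such as cell (79.4% of the lower against 56.5% of the higher genes) and binding (68.7% against 52.2%). Whether locomotion and immune system process go beyond a general difference in annotation was not tested. Hair follicle scores varied within both groups, at 0.08, 3.39 and 4.65 in AKBA replicates 1 to 3 and 2.19, 5.01 and 0.84 in control replicates 1 to 3. Across the 6 libraries they went with the cell cycle score (r = 0.899, exact permutation p = 0.0167; rho = 0.829, exact permutation p = 0.0583) and with the melanocyte score (r = 0.975, exact permutation p = 0.0111; rho = 0.886, exact permutation p = 0.0333). The adjusted p of r over these 2 relations was 0.0167 for each, and without the 2 libraries farthest from the median r was 0.726 and 0.951. Both relations were picked among many possible pairs of lists after the scores had been seen, which this adjustment does not cover. Each group holds 3 libraries, too few for a correlation within it.

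Macrophage markers were lower with AKBA gel, beside lower dermal markers. The macrophage score differed by -0.53 ± 0.17 (SE) and the dermal score, the mean of the fibroblast and endothelial scores, by -0.39 ± 0.13. Its parts did not move alike in each library. Control replicate 3 had the highest macrophage (6.15) and endothelial (4.97) scores, but its fibroblast score (9.36) lay below that of AKBA replicate 3 (9.51). Skeletal muscle and adipocyte scores differed by 0.067 and -0.12 (SD of the control libraries 0.604 and 0.377). Markers of other tissue beside the epidermis thus did not all fall with the dermal ones. The macrophage score less the dermal score differed by -0.14 ± 0.16, so a smaller share of dermal tissue in the AKBA libraries may account for the lower macrophage markers. Fewer macrophages per amount of dermis stays open as a biological explanation of the gel, since the standard error leaves room for it. No histology was analysed here.

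Stress keratin and SPRR genes were lower with AKBA gel, and LCE1 genes higher, at a score difference of 1.03 ± 0.53 (SE) over 12 genes picked after they were seen to rise. A different share of keratinocytes would move keratinocyte lists alike. The stress score less the score of the whole terminal differentiation list differed by -1.97 ± 0.73 (SE), from -1.87 ± 0.67 and 0.09 ± 0.27. Here 2 standard errors end close to the bound set for this test, which was written after the values had been seen. With 3 libraries per group 2 standard errors are a short interval, so the test cannot decide on a different share of keratinocytes. As for a single extreme library, without control replicate 3 the stress median was 0.634 times its full size (-1.13 against -1.79), with 21 of 24 members below 0, which argues against it as the whole cause. Across genes, which are not independent replicates, the fold change had an absolute r of 0.0151 with the first component of the variation within groups (40.6% of it) and 0.619 with the second (25.9%), on which the medians of the stress and LCE1 genes lie at percentiles 99.4 and 3.93 (3.16 and 6.11 on the first, at the same end). The bound set in advance named only the first component, and by it the prediction of a shared axis within and between groups failed. The second component was picked after the values were seen, and it is the largest of 4 (0.296 for the third, 0.142 for the fourth). Its r is thus no independent support. Whether the groups differ along an axis that also varies among libraries treated alike stays open, as does an effect of the AKBA gel, untested.

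The 6 libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05. For genes past the threshold by edgeR the real split gave 0 and the highest other 1, with 10 splits at least as large. The DESeq2 count was 292 against 353 in the highest other (2 splits as large), and the count at an unadjusted p under 0.05 by edgeR was 2291 against 2321 (2 splits). For response lists the values were 6 and 10 (5 splits), for marker lists 7 and 10 (6 splits), and for members past the threshold over each list alone 47 and 39 (1 split, the real one). The split that set AKBA replicates 1 and 2 with control replicate 3 against the rest gave the 353 and 2321 genes, which points to a structure of the libraries beside their groups.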
